A study of Homo sapiens with 2 samples.

How the data were processed

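RNA was measured by sequencing in THP-1 cells, a human monocytic leukaemia line, in 2 libraries. One library came from cells in which CRISPR guides delivered by adeno-associated virus (AAV) removed the region that encodes the long noncoding RNA UMLILO, with its promoter left in place. The other came from control cells that received AAV vector plasmids expressing Cas9. Per the labels, transduction lasted 1.5 weeks, RNA was extracted with Trizol and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The labels give 1 library per group, so there were no replicates, no test across samples was run and no p-value is given.

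The deposited values are gene-level FPKM (fragments scaled to transcript length and library size), per the file headers. The same tables hold TPM, which sums to the same total in every library, per the file headers, and in each library TPM was FPKM multiplied by 1 constant, 1.48 in the knockout and 1.56 in the control library. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3 and the genome build GRCh38. The annotation release and the strand setting of the quantification are not given in the sources used here, so reads from a gene and an overlapping or antisense neighbour may have been assigned to either. Both tables list 58302 genes. FPKM summed to 673861 in the knockout and 639008 in the control library, and 23727 and 23798 genes were above 0. One FPKM cell of the knockout table, that of ALB, was malformed and was replaced by its deposited TPM divided by the constant of that library. Gene positions, biotypes and transcript lengths were taken from GENCODE release 29 on GRCh38. Of the 58302 identifiers, 58039 matched, and 17 of the 263 without a match were among the genes analysed.

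Differences were computed as log2(FPKM + 1), knockout minus control, for the 12983 genes with a mean FPKM of at least 1 over both libraries. On this scale the difference of a gene with low expression is understated. A gene was counted as higher or lower when the difference reached 1, that is 2-fold, which is a rule of size and not a test. Folds in the text are ratios of FPKM. The depth of the libraries was estimated from the lowest values of genes with 1 annotated transcript. In FPKM multiplied by transcript length these values fell in steps, with the first peak at 38.9 in the knockout and 37.9 in the control library and the second peak at 2.00 times the first in both. A step of 1 fragment of that size implies about 25700000 and 26400000 fragments. Fragments per gene were approximated from this step and the longest annotated transcript. Exact (Clopper-Pearson) 95% intervals of ratios between the libraries were derived from them. The fragment numbers are approximate, and the intervals cover counting error only.

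Before the data were examined, 33 gene lists with 585 distinct gene symbols were fixed. They cover the chemokine cluster beside UMLILO, its flanking genes, other chemokines, NF-kB targets, the TNF and Toll-like receptor pathways, the WDR5-MLL1 complex, and interferon-stimulated and p53 target genes. Further lists hold monocyte, macrophage, granule and progenitor, and KMT2A-rearranged leukaemia genes, MHC class I and class II genes, proliferation genes, replication-dependent histones and immediate early genes. Metabolic and stress lists cover glycolysis, hypoxia, the respiratory chain, sterol synthesis, LXR targets, stress responses and heat shock proteins. The remaining lists hold ribosomal proteins, mitochondrially encoded genes, reference genes, DNA break repair genes, nuclear noncoding RNAs and markers of T and NK cells, B cells, erythroid cells and megakaryocytes, and epithelial cells and fibroblasts. For each list with at least 3 members past the expression filter, the median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A median under the 2.5 or over the 97.5 percentile was called outside the central range. This percentile describes these libraries, since genes are not replicates.

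The rule for named genes, also fixed before the data were examined, took UMLILO and all genes of the cluster and its flanks. It added the 12 protein-coding genes with the largest difference in each direction. From each list it took up to 4 members past the 2-fold rule, or otherwise up to 3 members with the highest expression. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

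Alternatives fixed in advance were pseudocounts of 0.1 and 5, scaling to TPM, scaling by the median ratio or by a mean of ratios trimmed by 30% of ratios and 5% of levels, no expression filter, a minimum mean FPKM of 5, a 1.5-fold rule, protein-coding genes only, and summing of rows that share a symbol. Random lists from protein-coding genes only, removal of a trend with transcript length, and leaving out small structured RNAs were chosen after seeing the data. The trend was removed among protein-coding genes, and the random lists were then drawn from these genes. The computation was tested on simulated data for the knockout against control comparison with 12983 genes. Of 200 genes simulated with a 4-fold difference, 198 (99.0%) passed the 2-fold rule and 0 other genes did, and 12 of 200 unchanged random lists fell outside the central range. The simulated noise was independent between genes and narrower than the spread of the real differences, whose SD was 0.53. These counts therefore check the computation and do not give error rates for the real libraries. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.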

Results

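The transcriptomes of UMLILO knockout THP-1 cells and of Cas9 control cells were compared, with 1 library each. UMLILO is a long noncoding RNA gene beside the CXC chemokine cluster of chromosome 4, and the comparison asks which genes differ in expression once its transcribed region is removed. The implied depth was about 25700000 fragments in the knockout and 26400000 in the control library. At that depth a gene with an FPKM of 1 and a transcript of 1 kb rests on about 26 fragments in either library. The libraries have no replicates, so every difference below describes this pair of libraries, and the UMLILO deletion cannot be separated from any other difference between the cultures. Nor can it be separated from a difference in the preparation of the libraries.

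UMLILO itself was listed at 0 FPKM in both libraries. The gene appears under the clone name AC112518.1 (ENSG00000228277) and is annotated on GRCh38 chromosome 4 from 73710302 to 73714527 on the plus strand. Its longest transcript has 575 bases in 3 exons, and its end lies 26.0 kb upstream of CXCL8. The deletion could therefore not be checked from the level of its target. With a limit of 3 fragments, a count of 0 allows up to 0.203 FPKM in the knockout and 0.198 FPKM in the control library. A listed 0 may also be a failed estimate, which was not tested. At 0 in the knockout library with 5 FPKM or more in the control library were 3 genes, and 5 genes the reverse. Within 1 Mb on each side of UMLILO, 21 of 39 annotated genes were at 0 in both libraries.

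Chemokine genes of the cluster were lower in the knockout library. CXCL8, which encodes the neutrophil attractant interleukin-8, was at 12.9 FPKM in the knockout and 20.1 FPKM in the control library. Its ratio was 0.641, with a counting interval of 0.576 to 0.713 from about 566 and 906 fragments. CXCL1 was at 1.54 against 2.85 FPKM, a ratio of 0.542 (0.369 to 0.793), and CXCL2 at 0.790 against 1.26 FPKM, a ratio of 0.629 (0.373 to 1.08). Of the 9 cluster genes, 6 had a lower FPKM in the knockout library, 0 had a higher one and 3 were at 0 in both libraries. None of them passed the 2-fold rule, and the counting intervals of CXCL2 and PPBP included equal levels. CXCL3, CXCL6 and PPBP could not pass it at their levels, since the rule uses log2(FPKM + 1). The FPKM ratios of CXCL3 and CXCL6 were 0.181 and 0.273.

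The remaining cluster genes rested on few fragments. CXCL3 was at 0.0588 against 0.326 FPKM, from about 2 and 14 fragments, and CXCL6 at 0.0787 against 0.289 FPKM, from about 3 and 13. PPBP was listed at 0 in the knockout library and at 0.186 FPKM, about 3 fragments, in the control library. PF4, PF4V1 and CXCL5 were at 0 in both. Summed over all 9 genes, the cluster had about 640 fragments in the knockout and 1059 in the control library, a ratio of 0.620 (0.561 to 0.685). Without CXCL8 the ratio was 0.496 (0.371 to 0.659). CXCL1, CXCL2 and CXCL3 are close paralogs whose reads can be assigned to one another, and their sum gave 0.532 (0.394 to 0.714). The median difference of the 3 members past the filter was -0.60, at the 0.99 percentile of random lists. With a pseudocount of 0.1 it was at the 2.71 percentile, inside the central range, and it was -0.26 with a pseudocount of 5 and -0.26 with no filter.

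**Figure D1:**
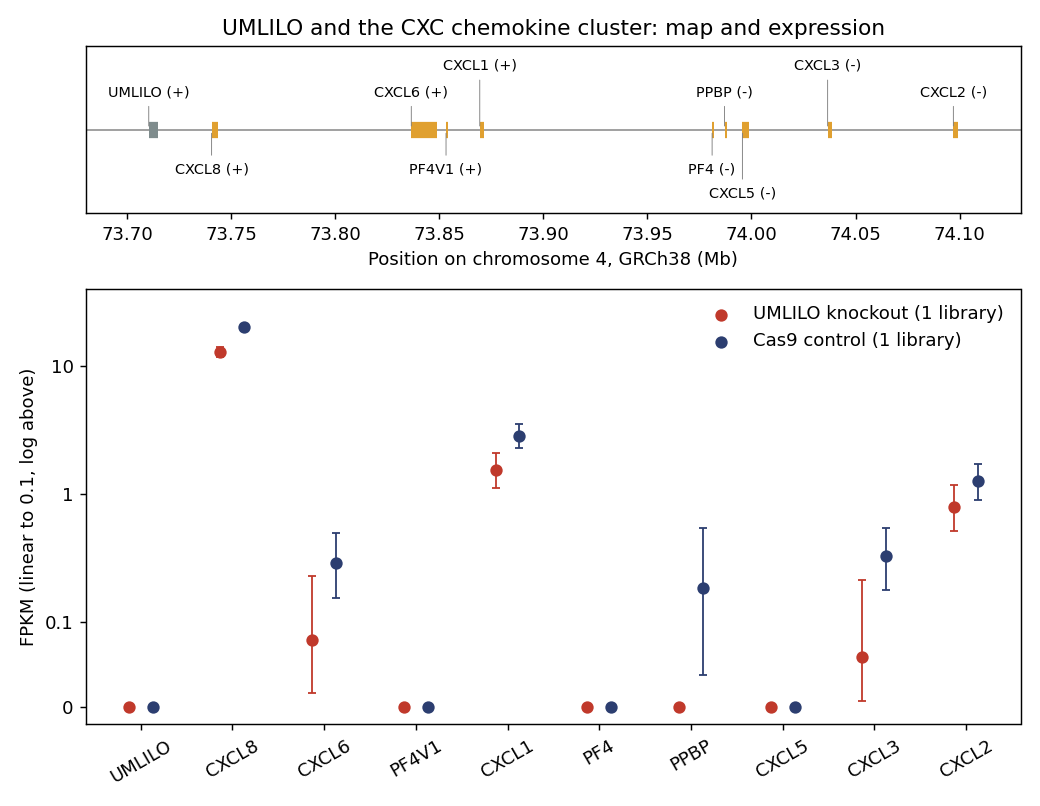
Upper panel, map of UMLILO and the 9 chemokine genes on GRCh38 chromosome 4 with their strands. Lower panel, FPKM of each gene in the knockout (red) and control (blue) library, on an axis that is linear up to 0.1 and logarithmic above, with exact Poisson 95% intervals from approximate fragment numbers that cover counting error only. CXCL8 was at 12.9 against 20.1 FPKM, and all 6 cluster genes with signal lie lower in the knockout library.

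Among the genes that flank the cluster, the 6 expressed members had a median difference of -0.01, at the 73.3 percentile. Of these, ANKRD17 and MTHFD2L lie within 1 Mb of UMLILO, whereas RCHY1, THAP6, G3BP2 and USO1 lie further away. The pseudogene HMGA1P2, chosen after its values were seen, also passed the filter within 1 Mb, at 2.74 against 5.64 FPKM. ANKRD17 was at 2.99 against 2.90 FPKM, MTHFD2L at 1.32 against 1.42, USO1 at 7.70 against 8.54, THAP6 at 2.1 against 1.73 and G3BP2 at 10.5 against 13.9. RCHY1, a ubiquitin ligase gene, was higher, at 6.47 against 2.40 FPKM. Of the other flanking genes, ALB was at 0.407 against 0.481 FPKM and PARM1 at 0.0233 against 0.0404. AREG was listed at 0.274 FPKM in the knockout library and at 0 in the control, and BTC at 0 and 0.0135. AFM, AFP, EREG, CDKL2, RASSF6 and EPGN were at 0 in both libraries. Chemokine genes elsewhere in the genome had a median difference of 0.01 over 7 members, at the 74.11 percentile. It was -0.12 at the 15.2 percentile with the transcript-length trend removed, and -0.13 at the 28.7 percentile with a minimum FPKM of 5. Of the 7 members 4 were above 0 and 3 below. Among them CCL5 was at 98.4 against 108 FPKM, CCL3 at 38.6 against 37.2 and CCL2 at 4.29 against 8.70, a ratio of 0.493. CCL4, chosen after its values were seen, was at 2.39 against 3.85 FPKM, a ratio of 0.622. The ratios of CCL2 and CCL4 were below that of CXCL8, so a decrease of that size was not limited to the cluster.

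Over the whole transcriptome, 299 of 12983 genes were at least 2-fold higher and 341 at least 2-fold lower in the knockout library, 4.93% together. Expression across genes correlated between the libraries with a Pearson r of 0.962 and a Spearman rho of 0.944, where genes are not independent replicates. The differences had a median of -0.07 and an SD of 0.53. Among the 10506 protein-coding genes 170 were higher and 307 lower. Small structured RNAs, such as spliceosomal, Y and 5S ribosomal RNAs, differed as a class from other genes. The class held the biotypes snRNA, rRNA, rRNA pseudogene, misc_RNA, snoRNA, scaRNA, ribozyme and scRNA. Its 176 genes had a median difference of 1.19, and 92 of them were 2-fold higher, 30.8% of all higher genes, against 4 that were lower. The size varied within the class, since its 66 snoRNA genes had a median of 0.31, with 24 higher and 2 lower. Outside the class, 33 miRNA genes (3 higher, 2 lower) and 21 mitochondrial tRNA genes (0 either way) each had a median of 0.15. Protein-coding genes with the shortest transcripts (207 to 1683 bases) had a median difference of 0.08, and the 7 length classes above them had medians between -0.13 and -0.04. Both differences limit the reading of the groups of short or non-polyadenylated RNAs described below. For those groups only the trend with transcript length was removed, with the values given there.

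**Figure D2:**
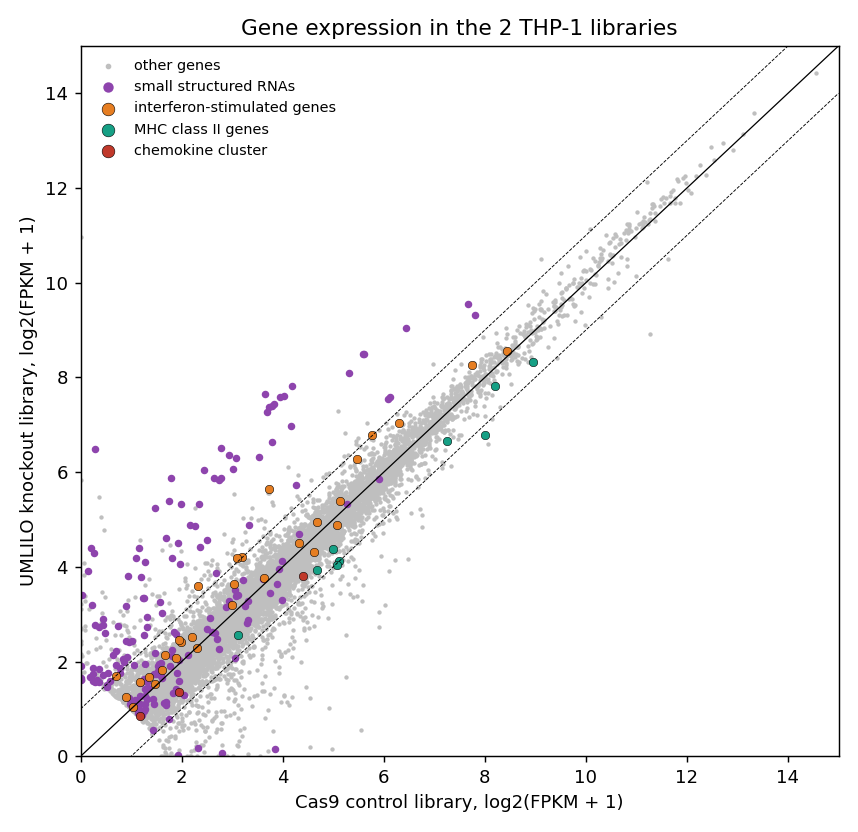
Expression as log2(FPKM + 1) of 12983 genes in the control library (horizontal axis) and the knockout library (vertical axis), with the solid line at equal levels and dashed lines at 2-fold. Small structured RNAs (purple, median difference 1.19) and interferon-stimulated genes (orange, 0.34) lie mostly above the line, and MHC class II genes (green, -0.64) and the 3 chemokine cluster genes past the filter (red, -0.60) lie below it.

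Monocyte genes were lower in the knockout library. Of 24 expressed monocyte identity genes, 21 were below 0 and 4 passed the 2-fold rule, and their median of -0.21 was at the 0.28 percentile. With the median ratio set to 0 or the trimmed mean their median was -0.13, at the 0.25 percentile. KLF4, a transcription factor of monocyte differentiation, was at 1.46 against 15.3 FPKM, and ITGAX, the integrin CD11c, at 8.68 against 46.7. CSF3R, the receptor of granulocyte colony-stimulating factor, was at 13.1 against 35.1 FPKM and the scavenger receptor gene CD36 at 4.0 against 9.83. MHC class II genes, which present antigen to T cells, were all below 0. Their 9 members had a median of -0.64, lower than each of the 10000 random lists. HLA-DRA was at 109 against 255 FPKM and HLA-DPA1 at 15.5 against 32.9. MHC class I genes had a median of 0.00 over 13 members, at the 35.7 percentile, with HLA-B at 817 FPKM in both libraries and B2M at 561 against 696.

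NF-kB target genes of the TNF response had a median of -0.26 over 20 members, at the 0.73 percentile, and 16 of them were below 0. TNFAIP2 was at 4.86 against 37.2 FPKM and IRF1, a transcription factor of the interferon response, at 1.36 against 5.26. Genes that encode the receptors and signalling proteins of the TNF and Toll-like receptor pathways had a median of -0.15 over 22 members, at the 14.3 percentile. One of them, the kinase adaptor gene TAB2, was higher, at 11.4 against 1.43 FPKM.

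Interferon-stimulated genes were higher in the knockout library. Of 30 expressed members 27 were above 0 and 5 passed the 2-fold rule, and the median of 0.34 was higher than each of the 10000 random lists. With a pseudocount of 5 it was 0.20. IFI27 was at 49.3 against 12.3 FPKM and IFITM1, which restricts virus entry, at 109 against 53.4. The antiviral GTPase genes MX1 and MX2, which are paralogs, were at 17.2 against 7.51 and at 11.1 against 4.01 FPKM.

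Sterol synthesis and uptake genes had a median of -0.44 over 16 members, lower than each of the random lists. In this group 14 members were below 0. CYP51A1, a demethylase of sterol synthesis, and INSIG1, which restrains it, were higher, at 36.8 against 3.78 and 95.5 against 42.5 FPKM. LXR target genes had a median of -0.31 over 8 members, at the 2.19 percentile, with the lipid synthesis genes SCD at 89.0 against 131 FPKM and SREBF1 at 21.8 against 23.8, and NR1H3, which encodes LXR-alpha itself, at 20.1 against 16.03. This median was inside the central range with a pseudocount of 5, at -0.14 and the 6.80 percentile, and with a minimum FPKM of 5, at the 10.98 percentile. Glycolytic enzymes had a median of -0.12 over 18 members, at the 2.29 percentile. GAPDH was at 2323 against 2234 FPKM. ALDOA had a difference of 0.39 and ENO1 one of -0.08, neither past the 2-fold rule, and that of ENO1 was 0.0011 with the trimmed mean. The glycolysis median was inside the central range under 6 of 10 alternatives, among them a pseudocount of 0.1, at the 2.52 percentile, and no filter, at the 7.34 percentile. It was -0.20 scaled to TPM and -0.04 with the median ratio set to 0 or the trimmed mean. After removal of the trend with transcript length, an alternative chosen after seeing the data, it was 0.0038.

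Cytosolic ribosomal protein genes, which have short transcripts, had a median of 0.24 over 30 members, at the 99.3 percentile, and 26 members were above 0. RPS23 was at 1450 against 556 FPKM and RPS3 at 2256 against 1088. Replication-dependent histone genes, whose mRNAs lack poly(A) tails as do most small structured RNAs, had a median of 0.36 over 7 members, at the 99.9 percentile. Of the 7 members 5 were above 0 and 2 below, and 14 of the 28 listed symbols were found. HIST1H4H was at 2.38 against 0.256 FPKM. With the transcript-length trend removed, the ribosomal protein median was 0.22 at the 99.91 percentile and the histone median 0.22 at the 97.68 percentile. With no filter the histone median was 0.63. In all, 10 of 30 lists with at least 3 expressed members lay outside the central range, 3 higher and 7 lower. By chance 1.5 would lie outside if genes within a list varied independently, as in the random lists. Genes of a list can vary together between cultures, so the 2 numbers do not measure an excess due to the deletion.

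**Figure D3:**
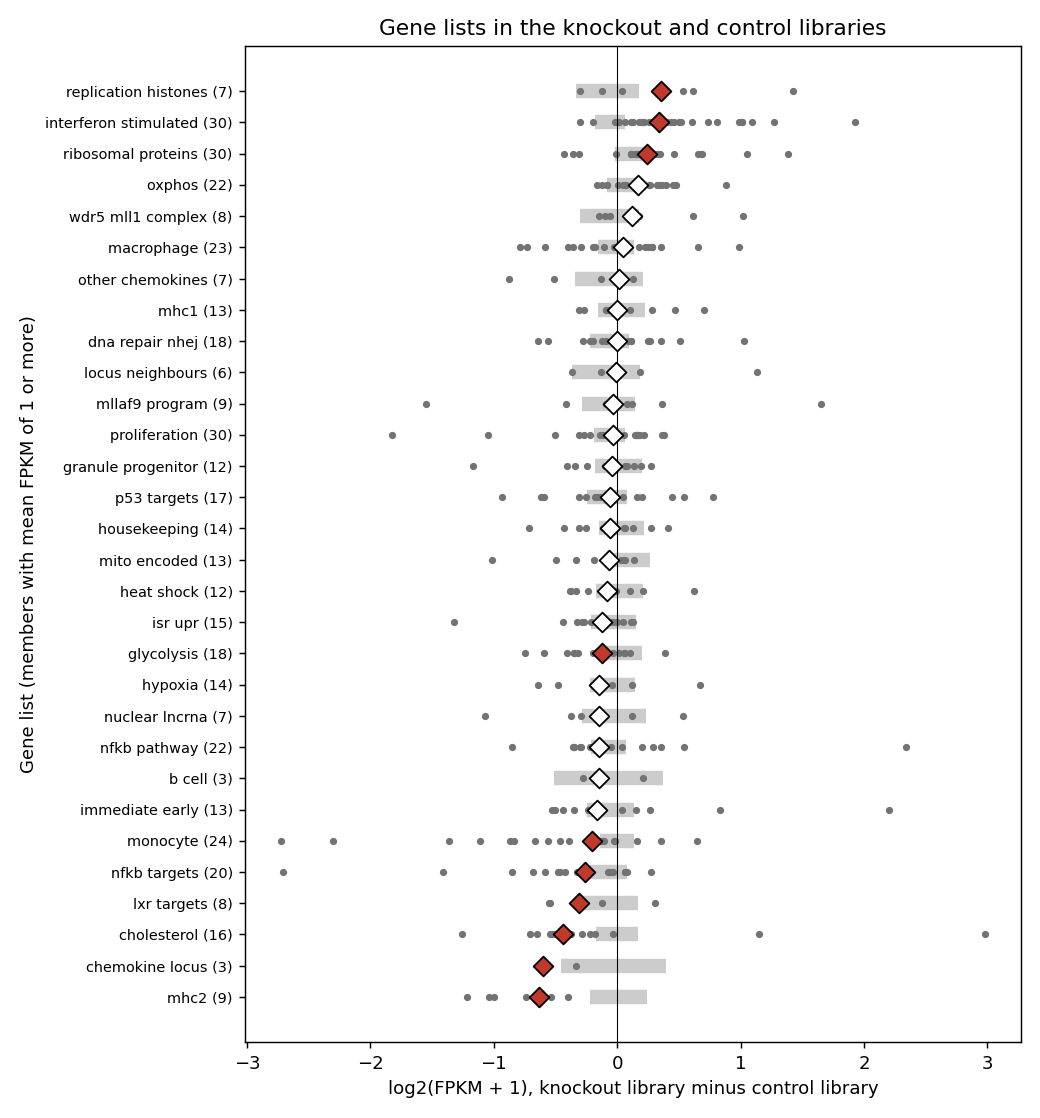
Median difference in log2(FPKM + 1), knockout minus control, of 30 gene lists (diamonds, filled red where outside the central 95% of 10000 random lists), with single members as grey points and the range of the random lists as grey bars. Member numbers stand in parentheses, and the diamonds run from -0.64 for MHC class II genes to 0.36 for replication-dependent histones.

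The other lists lay inside the central range at the main settings. Subunits of the WDR5-MLL1 complex, a histone methyltransferase, had a median of 0.12 at the 93.85 percentile, with HCFC1 at 15 against 6.87 FPKM. Respiratory chain subunits had a median of 0.17 at the 94.6 percentile, with COX6C at 481 against 344, COX4I1 at 467 against 446 and COX7C at 461 against 250 FPKM. With no filter they lay outside, at the 98.73 percentile. Proliferation genes had a median of -0.04 at the 67.0 percentile, although CCNA2 was at 3.03 against 13.31 FPKM and TYMS at 33.96 against 71.3. Targets of p53 had a median of -0.06 at the 62.2 percentile, with BAX at 91.4 against 103, CDKN1A at 29.2 against 30.3 and GADD45A at 17.1 against 14.8 FPKM. DNA break repair genes had a median of 0.00 at the 79.8 percentile, with ATM at 2.61 against 0.771 FPKM. Macrophage genes had a median of 0.04 at the 75.5 percentile, with CHI3L1 at 1009 against 1154, CTSB at 318 against 408 and SPP1 at 167 against 251 FPKM. Granule and progenitor genes had a median of -0.05 at the 28.98 percentile, with MYB at 4.99 against 12.4 FPKM. The KMT2A-rearranged leukaemia genes had a median of -0.04 at the 63.4 percentile, with PBX3 at 31.5 against 9.34 and JMJD1C at 8.42 against 26.6 FPKM.

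Stress and signalling lists were also inside. Immediate early genes had a median of -0.16 at the 13.29 percentile, with KLF6 at 6.13 against 0.552 FPKM. Hypoxia genes had a median of -0.15 at the 11.7 percentile, with NDRG1 at 126 against 145, DDIT4 at 106 against 165 and P4HA1 at 72.3 against 79.3 FPKM. Integrated stress and unfolded protein response genes had a median of -0.12 at the 16.2 percentile, with XBP1 at 7.70 against 20.7 FPKM. Heat shock proteins had a median of -0.08 at the 14.9 percentile, with HSPA8 at 771 against 668, HSPB1 at 527 against 343 and HSP90AB1 at 359 against 390 FPKM. Mitochondrially encoded genes had a median of -0.06 at the 3.63 percentile, with MT-ATP8 at 622 against 1257 FPKM. With the transcript-length trend removed their median was -0.20 and lay outside, at the 0.19 percentile. Reference genes of quantitative PCR had a median of -0.06 at the 13.0 percentile, with ACTB at 3278 against 3483 and PPIA at 1558 against 1424 FPKM. Nuclear noncoding RNAs had a median of -0.15 at the 16.9 percentile, with SNHG1 at 25.3 against 54.2 FPKM. The sign of the median differed between settings for 11 of the 30 lists, those of the flanking genes, other chemokines, p53 targets, granule and progenitor genes, leukaemia genes, MHC class I, proliferation, glycolysis, mitochondrial genes, reference genes and DNA break repair. Scaling alone moved the median of all genes by up to 0.07, which carries a median near 0 across 0 with little change in its percentile, whereas the length trend and the filter moved some percentiles further, as for other chemokines.

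Markers of other cell types were low in both libraries. Of the T and NK cell markers 1 passed the filter, NKG7 at 10.6 against 7.96 FPKM, and of the epithelial and fibroblast markers 1, THY1 at 2.39 against 2.06. None of the 13 erythroid and megakaryocyte markers passed, with highest values of 0.561 and 0.611 FPKM. The 3 B cell markers past the filter had a median of -0.15 at the 38.1 percentile, with CD79B at 6.55 against 5.54 and BANK1 at 1.41 against 1.92 FPKM.

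The protein-coding gene with the largest difference was the estrogen receptor gene ESR1, at 2008 FPKM in the knockout library and listed at 0 in the control. DCANP1 was at 56.3 against 0.00674 FPKM, FAM46A at 26.6 against 0.375, RASA4B at 15.96 against 0.0427 and AL121594.3 at 22.6 against 1.26. The transcription factor gene ADNP was at 9.37 against 0.0630 FPKM, NPIPB12 at 8.27 and listed at 0, and the actin crosslinker gene FLNA at 8.64 against 0.0557. DCTN4 was at 10.0 against 0.347 FPKM, CCSAP at 7.63 against 0.116 and NPIPB3 at 9.22 against 0.396, and CYP51A1 completed the 12 highest. RASA4B, NPIPB12 and NPIPB3 belong to families of near-identical copies and are uncertain for that reason. The others are uncertain as well, since a failed estimate in 1 library was not excluded for any of them. This holds for ESR1 too, at about 333582 fragments against 0.

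Among the 12 lowest, AC011448.1 was at 0.474 against 46.0 FPKM and AP002990.1 at 0.152 against 22.1. ADA2, a secreted adenosine deaminase of monocytes, was at 1.04 against 29.1 FPKM, THAP12 at 0.0792 against 12.1, NCOA4 at 2.18 against 36.9 and RCBTB2 at 1.34 against 22.4. PTGER4, a prostaglandin E2 receptor, was at 0.446 against 13.1 FPKM and the hormone precursor gene POMC at 0.0380 against 8.98. SEC61A1, a channel subunit of protein translocation into the endoplasmic reticulum, was at 5.60 against 58.7 FPKM. CLIC4 was at 1.11 against 16.3 FPKM, NIPSNAP1 at 1.74 against 21.03 and ZBED1 at 0.00977 against 7.12. Of these 24 genes, 7 overlap an annotated gene that differed in the opposite direction, which leaves the assignment of their reads uncertain, as for DCANP1 and TIFAB, the latter chosen after its values were seen, and 6 overlap no annotated gene.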

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

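Tests of the transcript-length trend, of protein-coding random lists and of leaving out small structured RNAs were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library was left out. Over all alternatives, the medians of lists other than the chemokine cluster kept their value within its spread in 240 cases, moved in 17 and reversed in 1, and that of the cluster moved under 5 of 8 alternatives. Only a list outside the central range at the main settings could be labelled reversed. Changes of sign in other lists were counted as kept or moved, and 11 of 30 medians changed sign between settings. The lists of MHC class II, sterol synthesis, interferon-stimulated, monocyte, NF-kB target, ribosomal protein and histone genes lay outside the central range under all 10 alternatives, the chemokine cluster under 8 of 9, LXR targets under 8 of 10 and glycolysis under 4 of 10. Mitochondrially encoded genes with the length trend removed and respiratory chain genes with no filter moved outside. No scaling moved the median of all genes by over 0.1.

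With a pseudocount of 0.1 the correlation was 0.941, the chemokine cluster median -0.64 and 13 of the 24 genes with the largest differences were the same. With a pseudocount of 5, which shrinks low genes, 139 genes were higher and 129 lower, the correlation was 0.973, the cluster median -0.26, the interferon-stimulated median 0.20 and 13 of the 24 genes were the same. Scaled to TPM, the correlation was 0.958, the cluster median -0.69 and the ribosomal protein median 0.16, and the last was 0.32 with the median ratio set to 0 and 0.32 with the trimmed mean. With no filter the correlation was 0.987 and the cluster median -0.26. With a minimum mean FPKM of 5, 160 genes were higher, 183 lower and the correlation was 0.948, and the cluster gave no value since fewer than 3 members were left. The 1.5-fold rule gave 632 higher and 912 lower genes, and protein-coding genes alone gave 170 higher genes. With the length trend removed the cluster median was -0.62, and the glycolysis median reversed to 0.0038. Apart from changes that follow from fewer genes or a larger pseudocount, the cause was not tested.

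The share of higher genes among those past the 2-fold rule was 46.7%, 41.1% scaled to TPM, 52.2% with the median ratio set to 0, 35.6% for protein-coding genes alone and 38.1% (207 higher, 337 lower) without small structured RNAs. Depth limits the cluster genes other than CXCL8, which together rest on about 74 fragments in the knockout and 153 in the control library.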

Other observations

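All tests below, of the length trend, counting error, NF-kB targets, few members, isoforms and overlapping genes, were chosen after the results were seen. Genes in the next paragraph were chosen after their values were seen.

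Small structured RNAs of several kinds were higher in the knockout library. RNU4-2 and RNU1-1, RNAs of the spliceosome, were at 200 against 11.6 FPKM and 225 against 17.2. RNY1, a Y RNA, was at 57.8 against 2.44 FPKM, and RN7SK, which holds back transcription elongation, at 526 against 86.4. RPPH1 and RMRP, the RNA parts of the ribonucleases P and MRP, were at 78.5 against 10.6 and 99.1 against 12.8 FPKM, and RN7SL1, the RNA of the signal recognition particle, at 749 against 201.4. All 9 genes of the biotype rRNA past the expression filter were at least 2-fold higher, with a median of 2.56. Of 11 rRNA pseudogenes 9 were higher, whereas the 2 mitochondrial ribosomal RNA genes had a median of 0.44 and 0 passed the 2-fold rule. Many of these genes have near-identical copies, so the split between copies is uncertain. With 1 library per group, a difference between the cells cannot be told apart from a difference in library preparation.

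The chemokine cluster was lower in the knockout library. Counting error of few fragments is argued against, since the upper bound of the pooled ratio was 0.685. A trend with transcript length was also argued against, because after its removal the median went from -0.60 to -0.62 and lay at the 0.735 percentile, or at the 0.84 percentile in a separate draw of random lists. Those lists held protein-coding genes only. Before removal the percentile was 1.815 against lists of protein-coding genes and 0.99 against lists of all genes. A lower level of NF-kB targets as a whole stays open and cannot be told apart from a shift of the cluster. The cluster median was at the 10.3 percentile of medians of 3 genes drawn from the NF-kB target list, between the bounds set for either outcome. Loss of UMLILO is a candidate explanation that 1 library per group leaves untested, beside any other difference between the cultures or the library preparations.

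Interferon-stimulated genes were higher in the knockout library. The length trend is argued against as the cause, since its removal moved the median from 0.34 to 0.43, at the 100 percentile. A few members with unstable estimates are argued against as well, because 28 of 30 members (93.3%) lay above the running median of genes of their level, where the upper limit of the central range of random lists was 66.7%. A response to the guide vector may contribute, as may the UMLILO deletion, and neither was tested, since the design confounds both with the library.

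Single protein-coding genes differed by 2-fold or more in 477 of 10506 cases, some with partner subunits at equal levels. SEC61A1 was at 5.60 against 58.7 FPKM, whereas SEC61B and SEC61G, chosen after their values were seen, were at 192 against 205 and 111 against 112. Counting error of few fragments is argued against as the cause, since Poisson counting gave 0 such genes on average over 100 simulations. Division of reads between isoforms is argued against as the cause of most cases, since 24 of 544 genes with 1 transcript (4.41%) and 453 of 9962 with more (4.55%) passed, a ratio of shares of 0.970 with a lower bound of 0.649, above the 0.5 set as the bar, in groups not matched on expression. For division between overlapping genes the shares were 3.49% of 3234 genes without and 5.01% of 7272 with an overlap, a ratio of 0.698 (0.568 to 0.859). Overlap was counted with any annotated gene on either strand, and these groups too were not matched on expression. Overlap may account for part of the cases, and it is argued against as the cause of most only if the groups are otherwise alike. Failed estimates of single genes and real differences stay open.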
